A study of Caenorhabditis elegans with 6 samples.

How the data were processed

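Total RNA of Caenorhabditis elegans, wild-type strain N2, was measured on 6 one-colour Affymetrix arrays. Per the labels' protocols, worms synchronised by bleaching were grown on bacterial plates for 48 h from the L1 to the L4 larval stage. They were then kept for 24 h at 20 °C in 50% M9 buffer, either alone (3 control arrays) or with 500 µg/mL BSA-SPION (3 exposed arrays). BSA-SPION are superparamagnetic iron oxide nanoparticles carrying a single layer of bovine serum albumin. RNA was extracted with Trizol and glass beads of 0.5 mm, cleaned on RNeasy columns and treated with DNase, and 200 ng was amplified with the NuGEN Ovation Pico WTA V2 kit into biotin-labelled cDNA, per the labels' protocols. The labels give the samples one stage, L4 hermaphrodite, and do not say whether the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. One control sample carries the number 3 in its title and the number 2 in its source label. The title was followed, and an alternative fit averaged controls 2 and 3 as 1 sample.

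The deposited values are log2 expression values, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set. The versions of these tools and the genome build of the array are not given in the sources used here, so no coordinates are printed. The log2 scale was read from the values, which lie between about 1 and 14 with no value below 0. The number of arrays, 3 per group, limits the precision. Scanner files and detection calls were not used here, so another background correction, normalization from raw intensities and a test of scan batches were not run. RMA compresses differences near the low end of the scale, so folds that start or end there understate the change.

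Of the 29317 deposited probe sets, 26192 carry a gene in the platform table and were tested. The other 3125 carry none there and stayed out of the test. Of the tested probe sets, 25546 carry 1 gene and 646 several. No gene is named from a probe set with several. Gene identifiers of 25495 probe sets matched NCBI RefSeq (assembly WBcel235, used for names and gene types only), and the match changed 0 symbols. Collagens, sperm-specific families and other multigene families have near-identical members, and their probe sets may read RNA of more than 1 member, so values of single members are uncertain.

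The values were used as deposited. Each probe set was fitted with limma 3.58.1 (lmFit and eBayes without trend, R 4.3.3), exposed against control, two-sided, with Benjamini-Hochberg adjustment over the 26192 probe sets and a threshold of 0.05. All adjusted p-values of single genes come from this fit. With 3 arrays against 3, an exact two-sided permutation test of a single gene cannot give a p under 0.1, so none was used. A second count took an unadjusted p under 0.05 and a change of at least 1.5-fold.

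Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 39 lists tested. Camera with an estimated correlation and limma's fry were run beside it. Fry asks whether the genes of a list move in one direction on balance, or, as its mixed p, change in either direction, without comparing them with other genes. Its directional p was adjusted over the 39 lists after the results were seen. List tests ran over 25478 genes, with the probe sets of a gene averaged (57 genes had more than 1). In this fit 934 genes passed the adjusted threshold, and the counts of list members come from it. A second count adjusted over the list alone. Of 40 lists written, the list of mitochondrially encoded genes had no member measured under its symbols and was not tested. In all, 37 list entries matched no measured gene. Families were formed from every symbol prefix with at least 8 measured genes (239 families) and tested with camera in the same way, with fry run beside it.

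The genes named follow a rule. They are the 8 largest rises and the 8 largest falls among probe sets of 1 gene past the adjusted threshold with separate groups, up to 4 members with the smallest p of each list that passed or held a called gene, and up to 3 members of each of the 3 leading families. To these come 12 genes reported whatever their values: ftn-1, ftn-2, smf-3, mtl-1, mtl-2, cdr-1, gst-4, sod-3, hsp-16.2, hsp-4, hsp-6 and vit-2. The rule takes 134 genes, of which 73 passed the adjusted threshold, not all of which are printed. The groups, tests, lists, naming rule and all alternatives but one were chosen before the data were examined.

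The procedure was tested on simulated data with the spread of the real arrays, in which 200 of 26192 probe sets were changed between exposed and control. It recovered 7% of those changed 2-fold and 89% of those changed 4-fold, with 6 false calls among 102 and 0 of the wrong sign. In 20 simulated draws with 1 list of 30 genes shifted by 0.5 on the log2 scale, camera found that list in 20 and called 0 of 780 other lists at the adjusted threshold. These simulated genes were independent of each other, which real genes are not. The real comparison gave more calls (959 against 102), so its adjusted threshold lay at a larger unadjusted p. The recovered percentages therefore hold for the simulated setting and not for the real comparison.

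The alternatives were a second quantile normalization, equal array medians, leaving out probe sets with a mean log2 value under 2.66, testing all deposited probe sets, 1 mean value per gene, eBayes with trend and robust settings, array weights, the replicate number as a block, controls 2 and 3 averaged, each array left out in turn, and an estimated correlation in camera. Leaving out both arrays numbered 3 was chosen after seeing that they stand apart.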

Results

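The arrays compared C. elegans hermaphrodites grown to the L4 stage and then kept for 24 h in buffer. The exposed group had albumin-coated iron oxide nanoparticles in the buffer and the control group had buffer alone, with 3 arrays per group. By the protocols L4 was the stage at the start of these 24 h, and the stage reached at harvest was not tested. The comparison asks which transcripts of the whole worm differ after the exposure. No arrays had albumin alone or uncoated particles, so effects of the iron oxide, the albumin and the particle load cannot be told apart. Array medians lay between 3.70 and 3.72 for exposed 1 and 2, at 3.89 for exposed 3, and between 3.97 and 3.98 for the controls (log2). Across probe sets, which are not independent replicates, arrays of the control group correlated with r of 0.963 to 0.988, those of the exposed group with r of 0.964 to 0.982, and arrays of different groups with r of 0.934 to 0.959. The first principal component held 48.6% of the variance and separated exposed from control arrays. The second held 23.4% and separated control 3 and exposed 3 from the other 4 arrays. No pair of arrays shared more than 36 identical values.

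Exposed worms had lower levels of several cuticle collagens, neuropeptides, synaptic genes and muscle genes, and higher levels of other collagens, sperm genes and the yolk gene vit-1. Of 26192 probe sets tested, 278 were higher and 681 lower in exposed worms at an adjusted p under 0.05, or 3.66% of those tested. Changes of at least 2-fold made up 245 of the higher and 629 of the lower calls, and changes of at least 4-fold made up 54 and 178. In all 959 the 3 exposed arrays lay entirely above or below the 3 controls, as they did for 28.2% of all tested probe sets, where chance gives 10%. Protein-coding genes made up 791 of the calls (of 18847 tested) and non-coding RNA genes 124 (of 5982). At an unadjusted p under 0.05, 5882 probe sets differed, where chance gives 1309.6, and with a change of at least 1.5-fold 2088 were higher and 2917 lower.

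The number of calls and their split by direction rested on single arrays and on the scaling. Without control 1 the total fell to 66, without control 2 to 53, without exposed 1 to 49 and without exposed 3 to 289, while it was 1996 without control 3 and 818 without exposed 2. With array weights 1330 were higher and 2143 lower, and without both arrays numbered 3 the numbers were 827 and 1490. Higher probe sets made up 29% of the calls as deposited, 41.5% after a second quantile normalization (427 higher, 603 lower) and 60.1% with equal array medians (598 higher, 397 lower). The median log2 change of all tested probe sets was 0.05 as deposited and 0.26 with equal medians, and changes are given below on the deposited scale. Of the 73 named genes that were called, 8 stayed called in the same direction under all 16 alternative settings: the collagens col-73, col-48, col-109 and col-65, the yolk gene vit-1, and C02E7.7, K01D12.9 and EGAP4.1. Without control 1, control 2 or exposed 1, 10, 8 and 9 of the 73 stayed called. Under all 9 alternatives that leave out no array, 50 of them stayed called.

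Of the 8 largest rises, 4 were in collagens. The collagen gene col-73 was 11.3-fold higher, from 3.43 ± 0.29 in controls to 6.93 ± 0.19 in exposed worms (log2, SD, n = 3), with an adjusted p of 0.0031. The collagens col-101 (10.3-fold), col-93 (9.48-fold) and col-135 (9.08-fold) rose too, with adjusted p-values of 0.010, 0.024 and 0.017. So did nspd-7, of a peptide family expressed in sperm (8.18-fold, adjusted p = 0.021), and E02H9.7, T08B2.12 and spig-20, by 10.3-fold, 9.34-fold and 8.16-fold. The largest falls were steeper. C02E7.7 was 30.9-fold lower, from 10.07 ± 0.60 to 5.13 ± 0.50 (adjusted p = 0.0064), and the collagen col-167 was 30.2-fold lower, from 9.99 ± 0.94 to 5.07 ± 0.89 (adjusted p = 0.012). The other large falls were in R74.2 (23.2-fold), K01D12.9 (22-fold), the collagen col-74 (21.3-fold), EGAP4.1 (21.2-fold), gmd-2, which encodes a GDP-mannose dehydratase (20.5-fold), and phat-5, of a family expressed in pharyngeal glands (20.1-fold). The call of gmd-2 (adjusted p = 0.047) was lost without any of control 1, 2 or 3, exposed 1 or exposed 3, with adjusted p-values up to 0.146, and it was kept in 6 of the 9 alternatives that leave out no array. Apart from col-73, C02E7.7, K01D12.9 and EGAP4.1, every gene of this group lost its call without control 2 and most of them without control 1 or exposed 1, with the same direction. Without exposed 3, col-93, T08B2.12, col-135, spig-20 and col-74 lost theirs too, and col-74 also with controls 2 and 3 averaged.

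**Figure D1:**
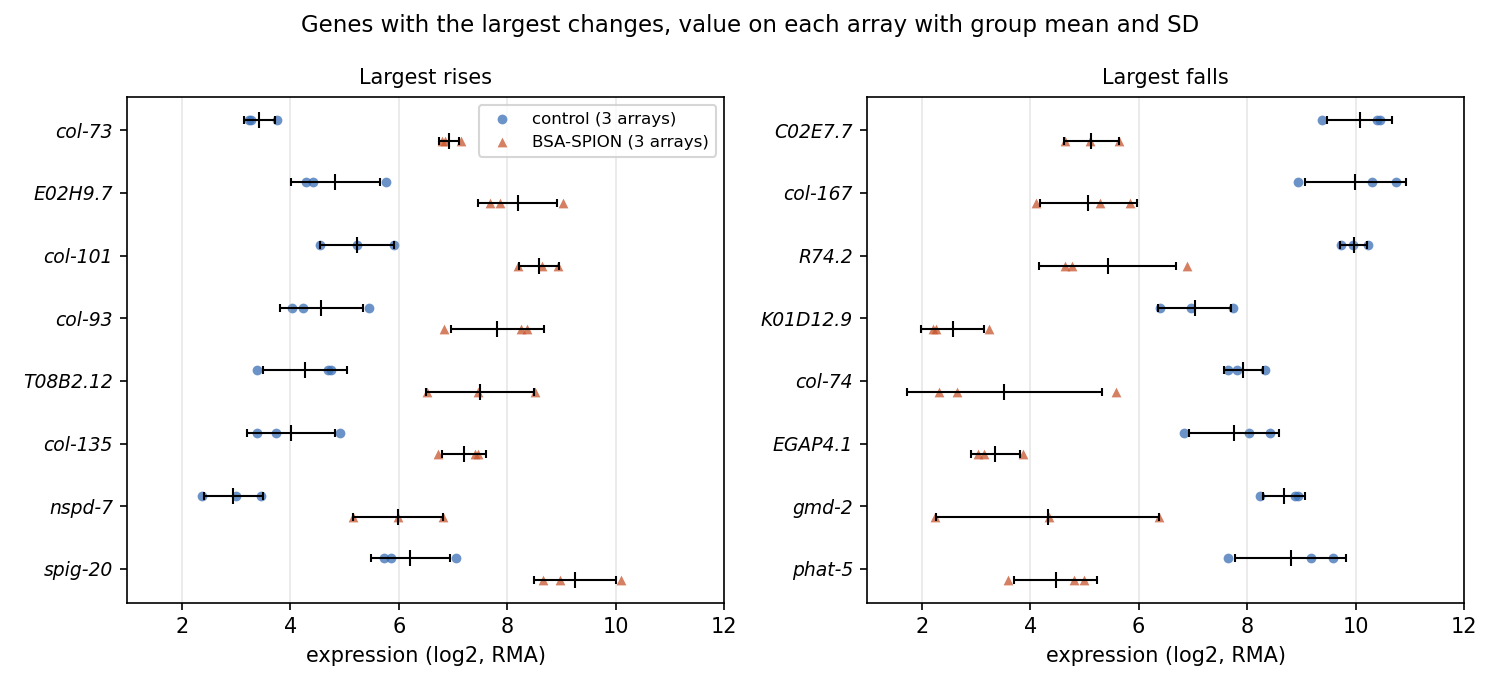
Log2 expression (x axis) of the 8 genes with the largest rise and the 8 with the largest fall, with 1 point per array (circles, 3 control; triangles, 3 BSA-SPION), black ticks at the group means and bars of 1 SD. The exposed arrays of col-73 lie between 6.79 and 7.14 against 3.25 to 3.76 in controls, while those of gmd-2 spread from 2.25 to 6.37.

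Cuticle collagens, the structural proteins of the worm's outer cover, changed in both directions. Of 176 measured, 8 were higher and 20 lower (14 and 29 adjusted over the list alone), and 148 did not pass. Among the falls, col-48 went from 7.52 ± 0.20 to 3.94 ± 0.27 (12-fold lower, adjusted p = 0.0031), col-65 was 15-fold lower (adjusted p = 0.0073) and col-109 was 3.95-fold lower (adjusted p = 0.0065). These 3 and col-73 kept their calls without each array in turn. The list as a whole did not pass camera. Its median log2 change was 0.09, its mean was -0.20, and camera gave an adjusted p of 0.774 for a fall, while fry's mixed p, for change in either direction, was 2.6e-05. This mixed p was under 0.05 for 30 of the 39 lists. The median turned to -0.01 when dim probe sets were left out.

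**Figure D2:**
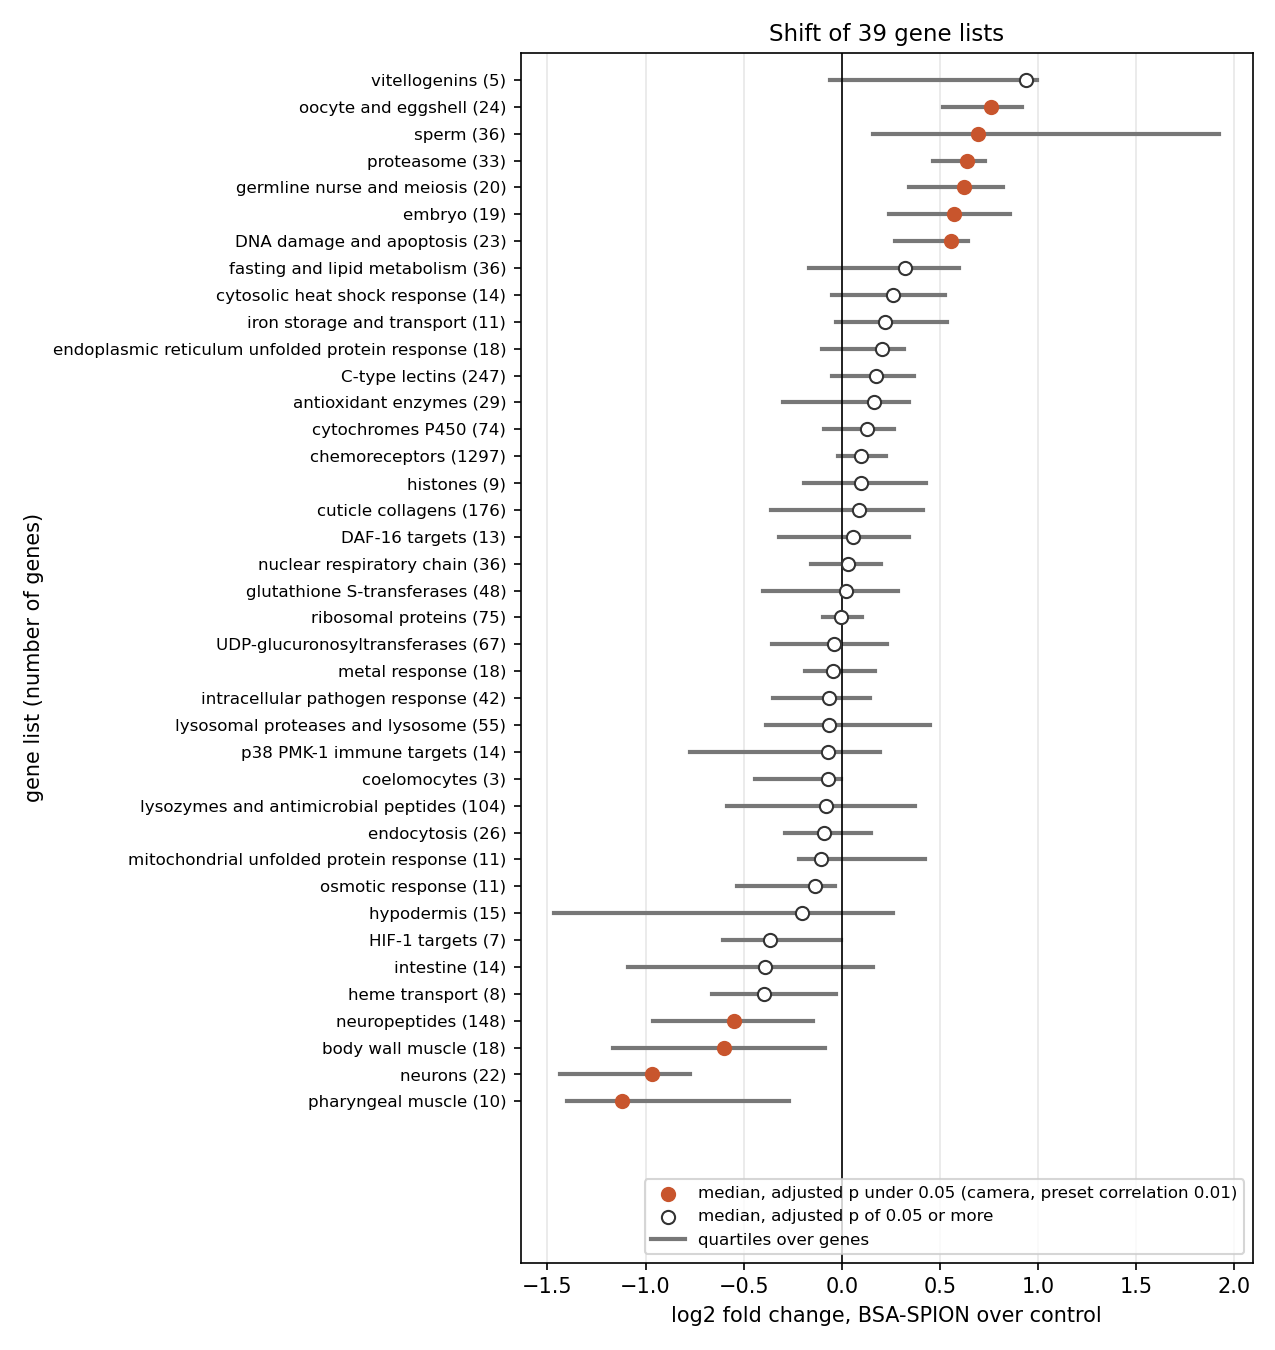
Median log2 fold change of exposed over control worms (x axis) for each of 39 gene lists, with bars over the quartiles of the member genes. Filled points mark the 10 lists with an adjusted p under 0.05 in camera at the preset correlation, none of which passed with an estimated correlation. Of these, pharyngeal muscle alone passed in fry's directional test.

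Neuronal transcripts were lower in exposed worms. Of 22 neuron genes 6 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 change of -0.97 and an adjusted p of 1.0e-09 in camera (adjusted p = 0.557 with an estimated correlation). They include synaptic vesicle release genes. The synaptotagmin gene snt-1 went from 8.29 ± 0.45 to 6.11 ± 0.16 (4.54-fold lower, adjusted p = 0.012), the SNAP-25 gene ric-4 was 3.87-fold lower (adjusted p = 0.0105), the synaptogyrin gene sng-1 3.28-fold lower (adjusted p = 0.014) and the syntaxin gene unc-64 2.15-fold lower (adjusted p = 0.028). Neuropeptide genes were lower as a list: of 148, 13 fell and 0 rose (50 and 2 adjusted over the list alone), with a median of -0.55 and an adjusted p of 9.6e-12 (adjusted p = 0.557 with an estimated correlation). The neuropeptide genes nlp-76 and nlp-35 were 4.32-fold and 3.30-fold lower (adjusted p = 0.0094 and 0.011), and the insulin-like peptide gene ins-1 2.59-fold lower (adjusted p = 0.017). The fall lay in the families nlp (78 genes, median -0.69) and flp (31 genes, median -0.74). Of the 39 genes of the insulin-like family ins, 20 had a positive and 19 a negative log2 change, with a median of 0.01 (adjusted p = 0.466), and ins-1 alone passed. Control 3 had a mean over the neuron list of 6.06, against 6.78 and 6.88 in controls 1 and 2 and 5.44 to 5.60 in exposed arrays. Without control 1, control 2 or exposed 1, none of these 7 genes stayed called, with adjusted p-values up to 0.115 and all of them still lower. The call of unc-64 was also lost without exposed 2 or 3 and with equal array medians.

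Muscle genes were lower as well. Of 18 body wall muscle genes 3 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.60 and an adjusted p of 1.5e-04 in camera (adjusted p = 0.557 with an estimated correlation). The troponin I gene tni-1 went from 9.57 ± 0.63 to 7.20 ± 0.84 (5.18-fold lower, adjusted p = 0.044), and dim-1 and the troponin T gene mup-2 were 2.38-fold and 2.34-fold lower (adjusted p = 0.021 and 0.049). The body wall myosin gene myo-3 was 3.16-fold lower with an adjusted p of 0.090 and did not pass. Of 10 pharyngeal muscle genes 3 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -1.12 and an adjusted p of 8.3e-04 (adjusted p = 0.557 with an estimated correlation, unadjusted p = 0.018). These were the myosin genes myo-5 (2.89-fold lower) and myo-1 (2.36-fold lower) and the troponin C gene tnc-2 (2.0-fold lower), with adjusted p-values of 0.025, 0.046 and 0.038. The calls of all 6 genes were lost without control 1, control 2, exposed 1 or exposed 3, with adjusted p-values up to 0.159, and those of tni-1, mup-2, tnc-2 and myo-1 also with equal array medians. Of the 9 alternatives that leave out no array, tni-1 kept its call in 7, tnc-2 in 6, mup-2 in 5 and myo-1 in 4. The calls of mup-2, myo-5, tnc-2 and myo-1 were lost without exposed 2, and that of myo-1 also without control 3.

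Sperm genes were higher in exposed worms. Of 36 measured, 6 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.70 and an adjusted p of 5.1e-07 in camera (adjusted p = 0.557 with an estimated correlation). Among them nspd-10 went from 4.54 ± 0.47 to 7.04 ± 0.77 (5.67-fold higher, adjusted p = 0.027), nspd-1 was 6.50-fold higher (adjusted p = 0.043) and ssp-34 3.69-fold higher (adjusted p = 0.029). The major sperm protein genes are read mostly by probe sets that carry several genes. Of 30 such probe sets, 6 were higher and 0 lower, with a median log2 change of 1.87. Their means were 5.07, 5.14 and 5.82 in controls 1, 2 and 3 and 7.35, 6.23 and 7.77 in exposed 1, 2 and 3. Control 3 and exposed 2 thus lay near each other. The 3 genes named lost their calls without control 1, control 2, exposed 1 or exposed 3, with adjusted p-values up to 0.142, all still higher. Of the 9 alternatives that leave out no array, nspd-1 kept its call in 6.

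Oocyte, germline and embryo lists were also higher, without any member past limma's adjusted threshold over all genes. The oocyte and eggshell list (24 genes, 12 higher and 0 lower at an unadjusted p under 0.05, 1 and 0 adjusted over the list alone) had a median of 0.76 and an adjusted p of 7.2e-05 in camera (adjusted p = 0.631 with an estimated correlation). The germline and meiosis list (20 genes, 10 higher and 0 lower at an unadjusted p under 0.05, 4 and 0 adjusted over the list alone) had a median of 0.62 and an adjusted p of 2.6e-04 (adjusted p = 0.631 with an estimated correlation). The embryo list (19 genes, 9 higher and 1 lower at an unadjusted p under 0.05, 4 and 1 adjusted over the list alone) had a median of 0.57 and an adjusted p of 9.5e-04 (adjusted p = 0.557 with an estimated correlation). The values of single members did not pass: mei-1, a katanin subunit of the meiotic spindle, was at 7.31 ± 0.22 in controls and 8.28 ± 0.24 in exposed worms (adjusted p = 0.052), the yolk receptor gene rme-2 at 6.65 ± 0.56 and 7.83 ± 0.21 (adjusted p = 0.078), and the P granule helicase gene glh-1 at 7.71 ± 0.39 and 8.70 ± 0.30 (adjusted p = 0.084). Both arrays numbered 3 had the lowest means of their group over the oocyte list: control 3 was at 7.82 against 8.46 and 8.67, and exposed 3 at 8.55 against 9.17 and 9.22, so that exposed 3 lay below control 1. On the germline list control 3 was at 6.85 against 7.62 and 7.68, and exposed 3 at 7.63 against 8.14 and 8.17. The embryo list differed: control 3 had the highest control mean, 4.30 against 3.66 and 3.69, and lay near the exposed arrays at 4.38 to 4.55.

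Among the yolk protein genes, vit-1 rose from 4.71 ± 0.18 to 6.87 ± 0.13 (4.49-fold higher, adjusted p = 0.0064), and this call was kept without each array in turn. The list of 5 vitellogenins did not pass (1 higher, 0 lower, also adjusted over the list alone, median 0.94, adjusted p = 0.132), though it passed without control 3 (adjusted p = 0.042). Its means were higher in each exposed array (8.90 to 9.42) than in any control (8.23 to 8.81), with a p of 0.014 in fry (adjusted p = 0.090). The brightest of them, vit-2, was at 12.32 ± 0.25 in controls and 12.26 ± 0.15 in exposed worms, and the sign of its change turned with equal array medians.

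Proteasome genes and genes of DNA damage and apoptosis passed camera as higher lists. All 33 proteasome genes had a positive log2 change, 0 passed over all genes in limma, 17 were higher at an unadjusted p under 0.05 and 10 passed as higher adjusted over the list alone, with a median of 0.64 and an adjusted p of 1.1e-08 in camera (adjusted p = 0.557 with an estimated correlation). The core subunit gene pbs-1 was at 8.48 ± 0.09 in controls and 9.16 ± 0.16 in exposed worms (adjusted p = 0.081). Of 23 genes of DNA damage and apoptosis 0 passed over all genes or adjusted over the list alone in limma (8 higher and 1 lower at an unadjusted p under 0.05), with 21 positive log2 changes, a median of 0.56 and an adjusted p of 6.5e-04 in camera (adjusted p = 0.557 with an estimated correlation). Its members with the smallest p were rnr-1 and rnr-2, subunits of ribonucleotide reductase, with log2 changes of 0.81 and 0.58 (adjusted p = 0.084 and 0.094). Control 3 had the lowest proteasome mean of all arrays, 8.01, against 8.62 and 8.68 in the other controls and 8.80 to 9.21 in exposed arrays. On the DNA damage list the groups overlapped: the controls were at 6.72, 6.64 and 6.24 and the exposed arrays at 7.13, 7.09 and 6.69, so that exposed 3 lay below control 1, and both arrays numbered 3 were lowest in their group. The oocyte and germline lists had similar medians (0.76 and 0.62), also with the arrays numbered 3 lowest in their group. Whether the proteasome and DNA damage lists moved apart from these was not tested.

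No iron, heme or metal list passed camera. The means of the iron and heme lists separated the groups, as did those of many other lists. Among these were the osmotic response, hypodermis and cuticle collagen lists, which did not pass either. Of 11 iron storage and transport genes 0 passed in limma, also adjusted over the list alone (3 higher and 0 lower at an unadjusted p under 0.05), with a median of 0.22 and an adjusted p of 0.134 in camera. Their mean was higher in each exposed array (6.03 to 6.21) than in any control (5.84 to 5.95), and fry gave a p of 0.021 for a rise (adjusted p = 0.103). The ferritin gene ftn-1, which is induced by iron, was at 9.05 ± 0.33 in controls and 9.77 ± 0.02 in exposed worms, higher in all 3 exposed arrays than in any control, but with an adjusted p of 0.104. It stayed higher under all 16 alternative settings (log2 change 0.54 to 0.93) and passed in 1 of them (adjusted p = 0.038 in limma). The other ferritin gene, ftn-2, was at 10.85 ± 0.04 and 10.79 ± 0.31, and the iron importer gene smf-3 at 5.98 ± 0.17 and 5.82 ± 0.34 (adjusted p = 0.884 and 0.716). Of 8 heme transport genes hrg-6 fell (3.55-fold lower, adjusted p = 0.044; 2 lower adjusted over the list alone), and the list did not pass (median -0.40, adjusted p = 0.066) except without control 2 (adjusted p = 0.037). Its means lay at 5.07 to 5.18 in exposed arrays and at 5.47 to 5.72 in controls, and fry gave a p of 0.010 for a fall (adjusted p = 0.090). Of 18 metal response genes only cdr-2, of the cadmium-responsive family, passed (4.25-fold lower, adjusted p = 0.023; 1 higher and 1 lower adjusted over the list alone), and the list median was -0.04 (adjusted p = 0.864), with array means that overlapped, a p of 0.623 in fry and a mixed p of 2.4e-06. The metallothionein genes mtl-1 and mtl-2 differed by 0.06 and -0.17 and cdr-1 by -0.08 on the log2 scale (adjusted p = 0.918, 0.677 and 0.827). The signs of ftn-2, smf-3, mtl-2, cdr-1 and the metal list turned with equal array medians, and that of mtl-1 with a second quantile normalization. Both called genes lost their calls without control 1, control 2 or any exposed array (adjusted p up to 0.145). The call of hrg-6 was also lost under both rescalings and with all deposited probe sets tested.

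**Figure D3:**
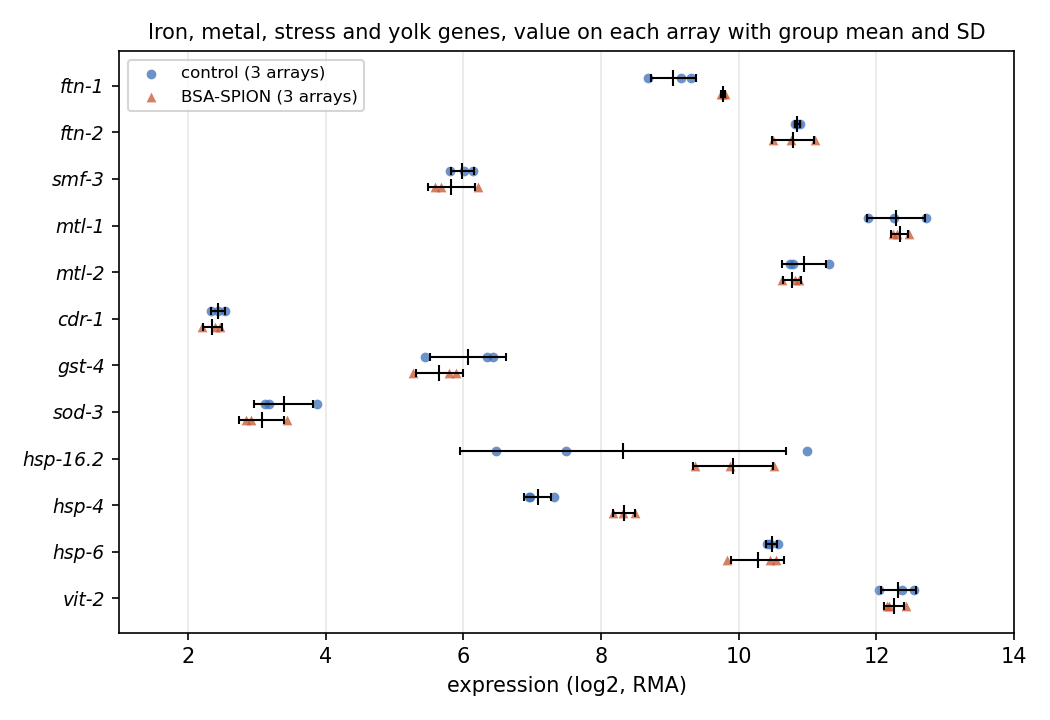
Log2 expression (x axis) of 12 iron, metal, stress and yolk genes, with 1 point per array (circles, 3 control; triangles, 3 BSA-SPION), black ticks at the group means and bars of 1 SD. The exposed arrays lie above all controls for hsp-4 and ftn-1, of which hsp-4 passed the adjusted threshold, and the controls of hsp-16.2 spread from 6.47 to 10.99.

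Of the stress responses, the endoplasmic reticulum chaperone gene hsp-4 rose from 7.08 ± 0.20 to 8.33 ± 0.16 (2.38-fold higher, adjusted p = 0.022), a call lost without control 1, control 2, exposed 1 or exposed 3 (adjusted p up to 0.097). It was the only one of 18 genes of the endoplasmic reticulum unfolded protein response to pass (also adjusted over the list alone), and the list did not (median 0.20, adjusted p = 0.203). The small heat shock gene hsp-16.2 was at 9.88, 9.36 and 10.51 in exposed worms and at 6.47, 7.50 and 10.99 in controls 1, 2 and 3. The difference did not pass with all arrays as deposited (adjusted p = 0.413). It kept its direction under all 16 alternative settings (log2 change 0.67 to 2.93) and passed in 2 of them (smallest adjusted p = 0.017 in limma). Of 14 cytosolic heat shock genes measured 0 passed in limma (2 higher and 1 lower at an unadjusted p under 0.05). The list did not pass camera (median 0.26, adjusted p = 0.477). Another 7 entries of this list matched no measured gene: daf-21, hsp-16.1, hsp-16.11, hsp-16.48, hsp-16.49, F44E5.4 and F44E5.5. The result therefore does not cover these genes. Of 11 mitochondrial unfolded protein response genes 0 passed over all genes (2 lower at an unadjusted p under 0.05 and adjusted over the list alone). Their list did not pass camera (median -0.11, adjusted p = 0.775), and its gene hsp-6 was at 10.48 ± 0.08 in controls and 10.27 ± 0.39 in exposed worms (adjusted p = 0.643). Of 29 antioxidant enzyme genes 0 passed (5 higher and 2 lower at an unadjusted p under 0.05; median 0.16, adjusted p = 0.725), with sod-3 at 3.39 ± 0.42 and 3.07 ± 0.33 (adjusted p = 0.541). No member of the lists of DAF-16 targets (13 genes, 2 higher and 2 lower at an unadjusted p under 0.05, median 0.06, adjusted p = 0.830), HIF-1 targets (7 genes, 2 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone, median -0.36, adjusted p = 0.311) and the osmotic response (11 genes, 1 lower at an unadjusted p under 0.05, median -0.14, adjusted p = 0.409) passed over all genes. The medians of the mitochondrial response and osmotic lists turned positive with equal array medians, and that of the DAF-16 list turned negative with a second quantile normalization. HIF-1 targets passed as lower without control 2 (adjusted p = 0.031), while their median was positive without control 3.

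Detoxification genes changed singly and in both directions. Of 48 glutathione S-transferase genes 1 rose and 2 fell (4 and 2 adjusted over the list alone): gst-29 was 4.52-fold higher, from 3.16 ± 0.24 to 5.33 ± 0.29 (adjusted p = 0.0087), and gst-22 and gst-3 were 1.98-fold and 2.24-fold lower (adjusted p = 0.030 and 0.044). The oxidative stress reporter gene gst-4 was at 6.07 ± 0.55 and 5.65 ± 0.34 (adjusted p = 0.478). Of 67 UDP-glucuronosyltransferase genes 2 rose and 3 fell (2 and 7 adjusted over the list alone), among them ugt-31, 2.68-fold higher, and ugt-17, 2.75-fold lower (adjusted p = 0.027 and 0.029). Of 74 cytochrome P450 genes cyp-13A5 alone passed (3.06-fold lower, adjusted p = 0.016; also adjusted over the list alone). None of the 3 lists passed camera, with medians of 0.02, -0.04 and 0.13 and adjusted p-values of 0.898, 0.377 and 0.377. In fry their p-values were 0.849, 0.059 and 0.025 (adjusted p = 0.895, 0.163 and 0.107), and their mixed p-values were 2.2e-06, 3.3e-05 and 7.0e-05. The glucuronosyltransferase means were lower in each exposed array (3.95 to 4.02) than in any control (4.06 to 4.12), and the cytochrome P450 means higher (3.70 to 3.75 against 3.64 to 3.65). The sign of the glucuronosyltransferase median turned with equal array medians. Without control 2 or exposed 1 each of these 6 calls was lost (adjusted p up to 0.147), and all but that of gst-29 also without control 1. Those of gst-22, gst-3 and ugt-17 were lost without exposed 2 or 3 too, and that of ugt-31 without exposed 2. With equal array medians, gst-22 and gst-3 did not pass, and the adjusted p of ugt-17 was 0.050. Of the 9 alternatives that leave out no array, gst-22 and ugt-17 kept their calls in 7 and gst-3 in 4.

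Genes of immunity and lysosomes also changed singly. Of the lysozyme and antimicrobial peptide genes 6 rose, 2 fell and 96 did not pass (6 higher and 3 lower adjusted over the list alone), with a list median of -0.08 (adjusted p = 0.623). The lysozyme gene lys-7 was 2.75-fold higher, ilys-5 2.27-fold higher and the saposin-like gene spp-4 3.39-fold higher (adjusted p = 0.042, 0.028 and 0.039), while the antibacterial factor gene abf-2 was 2.86-fold lower (adjusted p = 0.026). Of 247 C-type lectin genes 4 rose and 2 fell (3 and 1 adjusted over the list alone; list median 0.17, adjusted p = 0.059). They include clec-230, which went from 8.19 ± 0.17 to 4.63 ± 0.89 (11.8-fold lower, adjusted p = 0.012), and clec-223, 4.22-fold higher (adjusted p = 0.033). Of 55 lysosomal genes 3 rose and 0 fell (6 and 1 adjusted over the list alone; list median -0.07, adjusted p = 0.830), with the protease genes asp-13 and cpr-9 2.39-fold and 2.77-fold higher (adjusted p = 0.033 and 0.046). The third, cpr-8, passed at gene level and not in the fit over probe sets (adjusted p = 0.0505). Of 26 endocytosis genes the caveolin gene cav-2 fell 3.36-fold (adjusted p = 0.020) and no other passed (3 and 1 adjusted over the list alone; list median -0.09, adjusted p = 0.774). Of 14 targets of the p38 kinase PMK-1, K08D8.5 rose 2.65-fold (adjusted p = 0.024) and no other passed over all genes (1 and 1 adjusted over the list alone; list median -0.07, adjusted p = 0.794). Of 42 genes of the intracellular pathogen response 0 passed in limma (2 higher and 7 lower at an unadjusted p under 0.05; median -0.07, adjusted p = 0.411). With equal array medians, the negative medians among these lists turned positive. Each gene named as changed here lost its call without control 1, control 2 or exposed 1 (adjusted p up to 0.150), with the same direction. Without exposed 3 all but clec-230 and K08D8.5 lost theirs, and without exposed 2 so did spp-4, abf-2, clec-223, cpr-9 and K08D8.5. Of the 9 alternatives that leave out no array, lys-7 kept its call in 6, and spp-4, asp-13 and cpr-9 in 8. The C-type lectins passed as higher without exposed 2 (adjusted p = 0.017), and fry gave them a p of 0.046 (adjusted p = 0.158).

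Other tissue lists held few calls. Of 14 intestine genes the acid phosphatase gene pho-1 was 6.37-fold lower and the intermediate filament gene ifb-2 2.23-fold lower (adjusted p = 0.027 and 0.030; 5 lower and 1 higher adjusted over the list alone). The intestine list missed the threshold in camera (median -0.39, adjusted p = 0.057) but passed as lower in 10 of 15 other settings. Its adjusted p was 0.019 after a second quantile normalization, 0.030 with equal array medians and 0.035 with the replicate block. It was 0.011 without control 3, 0.029 without exposed 1 and 0.033 without exposed 2. With an estimated correlation it was 0.631. Of 15 hypodermis genes the collagen col-10 was 13.9-fold lower (adjusted p = 0.017; also adjusted over the list alone). The list did not pass (median -0.20, adjusted p = 0.179) but did without exposed 2 (adjusted p = 0.017), and with equal array medians its median was at 0.00. Of 1297 chemoreceptor genes 4 fell and 0 rose, and 0 passed adjusted over the list alone in limma (35 higher and 19 lower at an unadjusted p under 0.05), with srr-4 3.50-fold lower (adjusted p = 0.024). Their median was 0.10 (adjusted p = 0.057), and the list passed as higher with equal array medians (adjusted p = 0.0015) and without control 3 (adjusted p = 0.0051), exposed 1 (adjusted p = 0.015) or exposed 2 (adjusted p = 0.029). The chemoreceptor means were 2.29 to 2.54 over the arrays, under the limit of 2.66 used for dim probe sets. At this level a small rise may be one of the background, and equal array medians shift all genes of an array alike. No member passed over all genes in limma among 3 coelomocyte genes (1 lower at an unadjusted p under 0.05, median -0.07, adjusted p = 0.535, positive under both rescalings), 36 fasting and lipid metabolism genes (8 higher and 2 lower, median 0.32, adjusted p = 0.059), 75 ribosomal protein genes (2 lower, median -0.01, adjusted p = 0.794, positive with equal array medians), 36 nuclear genes of the respiratory chain (1 higher, median 0.03, adjusted p = 0.830) and 9 histone genes (2 lower, also adjusted over the list alone, median 0.10, adjusted p = 0.945, a positive median beside a camera direction of lower). The calls of pho-1, ifb-2, col-10 and srr-4 were lost without control 1, control 2 or exposed 1 (adjusted p up to 0.120), those of pho-1, ifb-2 and col-10 also without exposed 3, and that of ifb-2 without exposed 2. The calls of ifb-2 and srr-4 were kept in 8 of the 9 alternatives that leave out no array. Fasting and lipid metabolism genes, which missed the threshold in limma's camera, passed in limma's fry as higher (adjusted p = 0.024), with means of 7.32 to 7.37 in exposed arrays and 7.12 to 7.20 in controls.

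Among 239 gene families, 69 passed camera at the preset correlation, 29 as higher and 40 as lower. With an estimated correlation 0 passed after adjustment in camera (smallest adjusted p = 0.666), and 15 had an unadjusted p under 0.05. Of the lists, likewise, 10 passed at the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05. In fry's directional test, pharyngeal muscle alone of these 10 lists passed (adjusted p = 0.024). The others had adjusted p-values in fry from 0.090 (neurons and neuropeptides) to 0.240 (germline and meiosis). The F-box family fbxb led the families. Of its 108 genes 10 rose and 0 fell (28 and 0 adjusted over the family alone), with a median of 0.64 and an adjusted p of 1.3e-12 (adjusted p = 0.668 with an estimated correlation), and fbxb-22 was 3.44-fold higher (adjusted p = 0.027). The fbxb means were 3.25, 3.06 and 3.90 in controls 1, 2 and 3 and 4.07 to 4.19 in exposed arrays, so control 3 lay near the exposed arrays. In fry's directional test fbxb did not pass (adjusted p = 0.144). The nssp family had 9 falls and 0 rises among 84 genes (median -0.57, adjusted p = 1.4e-12; adjusted p = 0.666 with an estimated correlation), with nssp-63 5.02-fold lower (adjusted p = 0.020). The nlp family of neuropeptide-like proteins had 10 falls and 0 rises among 78 genes (median -0.69, adjusted p = 1.4e-12; adjusted p = 0.666 with an estimated correlation). The calls of fbxb-22 and nssp-63 were lost without control 1, control 2, exposed 1 or exposed 3 (adjusted p up to 0.108).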

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

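The 3125 probe sets that carry no gene in the platform table stood outside the comparison of named genes, and 59 of them passed the adjusted threshold when all deposited probe sets were tested together. Of these, 11 were higher and 48 lower in exposed than in control worms. They were singled out because they are a difference between the groups in data that the comparison of genes did not use. What they measure stays open here.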

How the results depend on the processing

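Leaving out both arrays numbered 3 was chosen after the data were seen. All other alternatives were planned. Of the 134 named genes under these settings, 1696 values kept direction and side of the threshold, 326 lost the call, 15 changed sign and the others gained a call. Of the list values, 506 stayed, 10 lost the call, 21 gained one and 48 changed sign, each of the sign changes in a list or gene that did not pass. Signal over background could not be weighed without detection calls, so how far dim probe sets limit the counts is open beyond the filter on dim probe sets, which gave 317 higher and 737 lower genes.

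The count of higher genes (278) became 427 after a second quantile normalization, 598 with equal array medians, 1330 with array weights and 827 without both arrays numbered 3. The count of lower genes (681) became 397 with equal array medians, 2143 with array weights and 1490 without both arrays numbered 3. The counts at 1.5-fold became 4231 higher and 1824 lower with equal array medians, which shift all genes of an array alike. With each array left out in turn, the higher genes ranged from 6 to 661, the lower from 43 to 1335, the 1.5-fold counts from 1714 to 2329 and from 2483 to 3248, the lists past the test from 10 to 14 and the families from 57 to 78. With an estimated correlation in camera, 0 lists and 0 families passed, against 1 and 15 at an unadjusted p under 0.05. Beyond these, the cause was not tested.

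The replicate block gave 326 higher and 652 lower genes, 11 lists and 62 families, and 62 of the 73 called named genes stayed called. Whether the equal numbers pair the samples stays open. Deviations from the group means correlated at 0.14, 0.08 and 0.25 for numbers 1, 2 and 3, and at -0.23 to 0.19 for unequal numbers. The highest value was that of the arrays numbered 3. Control 2 correlated best with exposed 1 (0.19), so not every sample correlated best with its own number.

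Sign changes of log2 values, none of them past the threshold and their cause not tested, were as follows. A second quantile normalization gave -0.031 for mtl-1, -0.031 for DAF-16 targets and 0.11 for coelomocytes. Equal array medians gave 0.14 for ftn-2, 0.046 for smf-3, 0.033 for mtl-2, 0.13 for cdr-1 and 0.14 for vit-2, and list medians of 0.16 for metal response, 0.17 for glucuronosyltransferases, 0.10 for the mitochondrial unfolded protein response, 0.13 for lysozymes, 0.14 for p38 targets, 0.14 for the intracellular pathogen response, 0.14 for lysosomal genes, 0.11 for endocytosis, 0.069 for the osmotic response, 0.20 for ribosomal proteins, 0.0013 for hypodermis and 0.13 for coelomocytes. Leaving out dim probe sets gave -0.057 for glutathione S-transferases and -0.0079 for collagens. Array weights gave 0.077 for vit-2, 0.0035 for metal response, 0.0052 for the intracellular pathogen response, 0.011 for lysosomal genes and 0.0071 for ribosomal proteins. Averaging controls 2 and 3 gave 0.0074 for vit-2. Without both arrays numbered 3, vit-2 was at 0.10, metal response at 0.039, glutathione S-transferases at -0.021, glucuronosyltransferases at 0.0032, the mitochondrial unfolded protein response at 0.059, the intracellular pathogen response at 0.058, lysosomal genes at 0.011, endocytosis at 0.064, HIF-1 targets at 0.042 and ribosomal proteins at 0.00054. With each array left out in turn, ftn-2 ranged from -0.22 to 0.081, mtl-1 from -0.14 to 0.27, mtl-2 from -0.28 to 0.0094, hsp-6 from -0.34 to 0.017 and vit-2 from -0.20 to 0.051. List medians ranged from -0.0497 to 0.0059 for metal response, from -0.035 to 0.12 for glutathione S-transferases, from -0.084 to 0.010 for glucuronosyltransferases, from -0.095 to 0.032 for the mitochondrial unfolded protein response, from -0.087 to 0.042 for the intracellular pathogen response, from -0.13 to 0.015 for lysosomal genes, from -0.21 to 0.15 for endocytosis, from -0.074 to 0.27 for DAF-16 targets, from -0.51 to 0.056 for HIF-1 targets, from -0.076 to 0.10 for the respiratory chain and from -0.066 to 0.033 for ribosomal proteins.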

Other observations

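Beyond the leading families, several smaller ones moved in camera at the preset correlation and not with an estimated one. The mcm genes, which encode the replicative DNA helicase, had 2 higher and 0 lower of 8 (median log2 change 1.0, adjusted p = 1.5e-04, and 0.666 with an estimated correlation). The nuclear pore genes npp had 1 higher and 0 lower of 26 (median 0.74, adjusted p = 4.4e-08, and 0.668), and the sdz genes 3 higher and 0 lower of 34 (median 0.64, adjusted p = 1.2e-05, and 0.666). On the other side, the dbd family had 8 lower and 0 higher of 19 (median -1.34, adjusted p = 1.2e-09, and 0.666), hot 4 lower of 9 (median -1.19, adjusted p = 1.2e-05, and 0.666) and the FMRFamide-like peptide genes flp 2 lower of 31 (median -0.74, adjusted p = 1.9e-09, and 0.666). The patched-related genes ptr had 4 lower of 24 (median -0.55, adjusted p = 8.3e-04, and 0.666).

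The counts of other splits were planned before the results were seen. The rules for the swap of control 3 and for the molting genes were set before these tests were run. They address patterns already seen in these data, however, so they were not chosen blind to the results. Criteria were later added to both rules, as given below. All other tests below were chosen after the results were seen. Of the 10 ways to split the 6 arrays into 3 and 3, too few for a share under 0.05, the real one gave 959 genes past the adjusted threshold against at most 0 in another split, and 1 split reached that number. At an unadjusted p under 0.05 and 1.5-fold it gave 5005 against 1303, also reached by 1 split. For families it gave 69 against 60, reached by 1 split. For lists it gave 10 against 13, and 4 of the 10 splits put as many past the test.

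Oocyte, germline, sperm and embryo lists were higher in exposed worms, and neuron and muscle lists lower. A trend with brightness left by the normalization is argued against. Random lists of the same size and brightness had typical medians of -0.002 to 0.15. Among 10000 such lists, the lowest percentile of the 4 higher medians was 99.99 and the highest of the 3 lower medians was 0. The tissue lists had been picked for passing camera, and the random draws treat genes as independent. The percentiles therefore add no support for the changes themselves. The third arrays are also argued against as the whole source, since the lowest of the 4 medians without both was 0.47. One common rise in the share of germline and embryo RNA would lift all 4 lists alike. Over all members the permutation p of a Kruskal-Wallis statistic was 0.709, with medians of 0.57 to 0.76, but many sperm genes lie near the low end of the scale, where changes are compressed. With only members above log2 5 on average that p was 0.0038, but a rise itself lifts genes over this cut, so it decides nothing. The 30 probe sets of major sperm protein genes rose more, with a median of 1.87 and quartiles of 1.6 and 2.2, against quartiles of 0.52 and 0.92 for oocyte genes and 0.34 and 0.82 for germline genes. Between arrays, however, their rise exceeded that of the oocyte list by 1.11 with an SE of 0.80 and that of the germline list by 1.17 with an SE of 0.79, and the arrays of the 2 groups overlapped in both. One common rise therefore cannot be told apart from a separate one in sperm genes, with 3 arrays per group. For the somatic lists, one common fall in their share of the RNA cannot be told apart from separate changes either (permutation p = 0.235). A different makeup of the worms, from slower or faster development or from the exposure, may contribute to both and was not tested further.

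The heat shock gene hsp-16.2 was high in control 3 and in all exposed arrays. A wrong label on an exposed sample is argued against over all probe sets. Control 3 correlated with the other controls at r of 0.963 and 0.964 and with exposed arrays at 0.941 to 0.950, a gap of 0.0134 where the wider of these ranges is 0.0092. On the first principal component it lay at -41.4, with the other controls at -53.1 and -58.9 and the exposed arrays at 36.3 to 64.1, and counting it as exposed gave 152 calls in place of 959. A swap with an exposed array is argued against too, since no such swap gave more than 0 calls, or more than 1303 against 5005 at an unadjusted p under 0.05 and 1.5-fold. With controls at 0 and the other exposed arrays at 1, the lowest median position of an exposed array was 0.61, for exposed 2. Its quartiles were 0.37 and 0.85. By the rule set before this test was run, a position nearer the exposed arrays counted against a swap. With these quartiles the position alone would not exclude one, so the counts after swaps were added to the rule. Over the 1996 genes called without control 3, its own median position was 0.45, with quartiles of 0.14 and 0.78. What made this control differ from the other 2 stays open.

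Collagens changing in both directions could come from another time in the molting cycle. Of 39 molting genes that are no collagens, 17 had an unadjusted p under 0.05, 4 higher and 13 lower, a number at percentile 91.3 among random lists matched on brightness (median 13). The number that random lists seldom exceed was 18, which lies within the binomial SD of 3.10 of the observed one. The 5 past the adjusted threshold were all lower: nas-6, ptr-6, wrt-4, ptr-18 and ptr-16, chosen after their values were seen. Exposed 2 had a mean of 6.07 over these genes, like the controls at 5.95 to 6.09, while exposed 1 and 3 were at 5.25 and 5.28. By the rule set before this test was run, a percentile of 91.3 counted against a shift in molting time. The comparison with the binomial SD was added to that rule, and with it such a shift is neither shown nor excluded.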
